A study of Mus musculus with 38 samples.

How the data were processed

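The deposited files were a scanner file for each of the 38 arrays and the submitters' series matrix. Values used were Cy3 signal intensities, background-subtracted, spatially and multiplicatively detrended within each array, with a surrogate value where a spot was not positive and significant, per the file headers. They were not scaled between arrays. The headers name Agilent Feature Extraction 10.7.1.1 and the submitters' notes 9.5.1.1. RNA was extracted with TRIzol, purified on columns and labelled with the Low Input Quick Amp kit, as the labels state. The series matrix holds linear intensities, deposited by the authors after quantile normalization. All 38 of its columns had a median of 19.14, differed by at most 0.00136 (relative) at equal rank, and correlated with their arrays at 0.996 or more on the log2 scale.

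Of 55681 non-control probes, 27235 were named through a RefSeq accession and 565 through a unique synonym in the gene table of assembly GRCm38.p6, and 3403 names were updated. Of all probes, 78 were left out because every spot was marked unusable on some array. The gene name column was empty on 6 arrays, whose probes were named by their identical order. No spot was saturated, and no column of values lacked a sample. Probes well above background on at least 4 of the 38 arrays were kept (33354), and each gene was represented by its probe with the highest mean, which gave 23337 genes, 6734 of them with several passing probes. In genes called with several probes, another probe had the other sign for 361 of 1994 in WT s_dissection against WT control, 227 of 805 in KO s_dissection against WT s_dissection and 136 of 388 in KO intact against WT intact.

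Log2 signals were scaled by subtracting each array's 75th percentile over non-control probes. Local background was 54 to 62. The floor of an array, its lowest scaled log2 signal among probes well above background, was -4.80 to -3.32. The number of arrays limits precision. Correlations between replicates were 0.952 to 0.992. The first 3 principal components held 36.6%, 10.4% and 5.6% of the variance. Groups followed the labels, whose titles write dissociation where other labels write dissection, taken as the same. The labels do not say that replicates are separate animals, so p-values measure the spread between samples.

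A model with 1 mean per group was fitted to all 38 arrays with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with 29 residual and 2.28 prior degrees of freedom and Benjamini-Hochberg adjustment within each of 16 comparisons. A gene was called at an adjusted p under 0.05. The comparisons were those of every group with WT control, as the series design states, KO with WT in each condition, intact with sham and s_dissection with intact in each genotype, KO with WT averaged over 4 conditions, and the interaction of genotype with stress in intact aorta. The single WT l_dissection array was described without a test, as the number of genes outside the range of the other 37 arrays and at least 2-fold from the WT control mean.

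Gene lists, comparisons, the naming rule and the alternatives first listed below were written before the data were examined. The 26 lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation as the alternative. Members were also counted with adjustment over the list alone. For WT l_dissection, list medians were set against 10000 random lists matched in size and in mean level (20 bins).

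Genes were named by rule. In 9 comparisons these were Socs3 and the 6 largest rises and 6 largest falls among called genes that were well above background on all arrays of the higher group and whose arrays did not overlap between the 2 groups. In the average, the sign had to be shared by all 4 conditions. In the other comparisons 3 and 3 were named. Genes with clone or predicted names were left out, and a few results that the rule selects are not reported here. Up to 4 members with the smallest adjusted p were named from each list described. Where no array of the dimmer group was well above background, values were raised to each array's floor, which makes the fold a lower bound.

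In simulated WT s_dissection against WT control (23337 genes) limma called 32.8% of 67 genes changed 1.5-fold. It called 65.7% of 67 at 2-fold and 84.8% of 66 at 4-fold. Unchanged genes were 6.9% of calls. For KO against WT control with no change simulated limma called 0. A shifted list and 0 of 200 unchanged lists were called. Unequal group spread, seen here, and correlation within lists were not tested.

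The alternatives were normexp background correction (offset 50), quantile normalization, no filter or a stricter filter on dim probes, the mean of a gene's probes, the series matrix, slide as a fixed or random block, fits within a slide or without slide 6, replicate number as a block, fits of only the groups compared, and each array left out in turn. Scan day as a block, fits within a scan day, leaving out 3 arrays, and subtraction of the sham difference were added later.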

Results

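RNA from the suprarenal aorta of C57BL/6 mice was hybridised to 38 single-colour Agilent arrays, 1 per sample. The series title names the question, the part that Socs3 in macrophages plays in aortic dissection. Socs3 encodes a feedback inhibitor of signalling by interleukin-6 family cytokines through STAT3. Mice were wild type (WT) or lacked Socs3 in macrophages (KO). Aortic stress was 0.5 M calcium chloride on the infrarenal aorta with angiotensin II at 1 µg/kg/min for 7 days. Control mice were untreated. Sham mice received physiological saline in place of calcium chloride, and the labels do not say whether they received angiotensin II. Stressed aortas were grouped by morphology as intact (no change seen), s_dissection (focal disruption of the media between the celiac trunk and the superior mesenteric artery) or l_dissection (dissection visible beyond these vessels). WT arrays numbered 4 control, 4 sham, 6 intact, 4 s_dissection and 1 l_dissection. KO arrays numbered 4 control, 4 sham, 7 intact and 4 s_dissection.

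Between 46.4% and 58.0% of spots per array were well above background, and the 75th percentile of the processed signal ran from 136 (WT s_dissection replicate 1) to 417 (KO s_dissection replicate 4). Levels are log2 signals relative to each array's 75th percentile, as mean ± SD over arrays. Differences are log2 values ± SE with Benjamini-Hochberg adjusted p-values from limma, over 23337 genes. For a gene not well above background on any array of the dimmer group, the fold is given as a lower bound ("at least"). Positions are those of the 60-base probes in genome build mm9 (NCBI37), as the files give them, and the files do not say which part of a transcript a probe lies in. The arrays lay on 6 slides scanned on 3 days. Day 3 held 17 arrays, of WT control, sham, intact, s_dissection and KO control. Day 1 held 14 arrays, of KO sham, intact and s_dissection. Day 2 was slide 6, with 1 array of each of 7 groups, KO intact and KO s_dissection not among them. KO intact and KO s_dissection arrays therefore shared no scan day with the WT arrays they were compared with.

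Socs3, the targeted gene (probe on chromosome 11, 117827480 to 117827539), is given first because it bears on the labels. Its level was 0.79 ± 0.14 in WT control, 1.19 ± 0.26 in WT sham, 1.46 ± 0.54 in WT intact and 2.05 ± 0.68 in WT s_dissection, and 4.80 on the WT l_dissection array. In KO it was 1.09 ± 0.32 in control, 1.18 ± 0.49 in sham, 1.72 ± 0.77 in intact and 2.81 ± 1.31 in s_dissection. Socs3 rose in WT s_dissection over WT control by 1.26 ± 0.45 (n = 4 and 4, adjusted p = 0.040) and in KO s_dissection over WT control by 2.01 ± 0.45 (adjusted p = 0.0018). Over the alternatives tried, the adjusted p of these rises ran from 0.016 to 0.30 and from 7.4e-05 to 0.29. The WT call was lost in 7 of the 8 fits that left out 1 array. Averaged over the 4 conditions, KO minus WT was 0.33 ± 0.22 (adjusted p = 0.38). No KO group had a lower level than its WT group by a difference that passed. The labels give neither the deleted part of the gene nor the Cre driver, and macrophages are 1 of many cell types in the wall, so this probe is a weak check of the genotype labels.

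**Figure D1:**
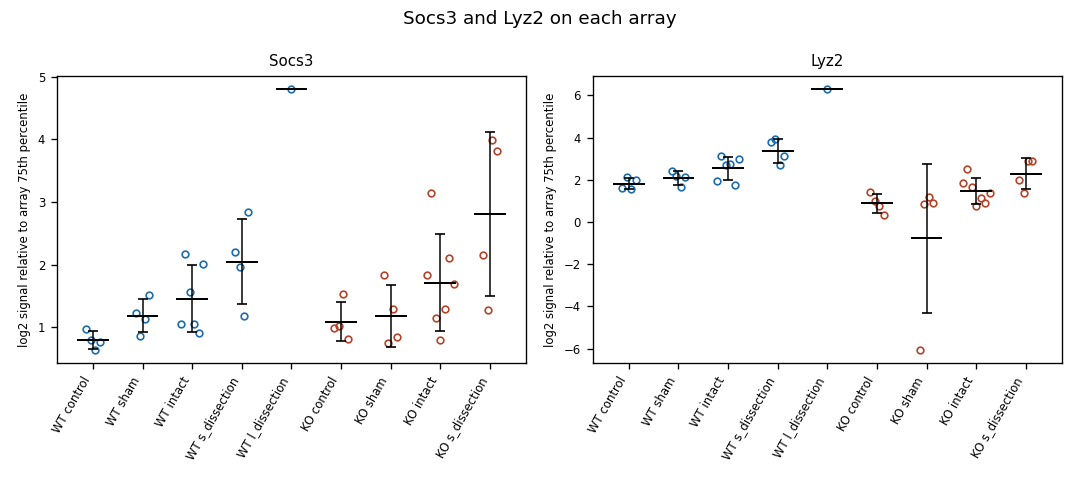
Level of Socs3 and of the macrophage lysozyme gene Lyz2 on each array, by group (y axis, log2 signal relative to the array's 75th percentile; points are arrays, bars are group means with SD error bars, blue WT, red KO). Socs3 means run from 0.79 in WT control to 2.81 in KO s_dissection among groups with replicates, and Lyz2 on KO sham replicate 1 lies at -6.07.

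The first comparison asked what stress does to WT aorta in which no lesion was seen (WT intact, n = 6, against WT control, n = 4). Matrix genes rose. Of 23 collagen and matrix assembly genes, 7 rose and 16 did not pass (12 rose and 1 fell adjusted over the list alone), among them Col3a1, the chain of type III collagen, 2.28-fold (1.19 ± 0.18, adjusted p = 0.00054; probe on chromosome 1, 45405589 to 45405648). Col1a1 of type I collagen rose by 1.14 ± 0.20 and the proteoglycan Bgn by 0.63 ± 0.13. Of 18 elastic fibre genes 6 rose and 12 did not pass (9 rose adjusted over the list alone). Elastin, Eln, rose 4.03-fold (from 3.76 ± 0.30 to 5.77 ± 0.64, adjusted p = 0.0011; chromosome 5, 135179129 to 135179188), and the microfibril genes Mfap2 and Mfap4 rose 3.71-fold and 2.56-fold. The metalloproteinase Mmp2 rose by 0.90 ± 0.21 and cathepsin K, Ctsk, by 0.90 ± 0.24, with 2 of 21 matrix protease and inhibitor genes passing (6 adjusted over the list alone).

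Genes of dividing cells also rose in WT intact aorta. Of 23 cell cycle genes 5 rose and 18 did not pass (14 rose adjusted over the list alone), with Mki67, a marker of cycling cells, 4.50-fold higher (adjusted p = 0.041), the cyclin Ccnb1 5.75-fold (adjusted p = 0.035) and topoisomerase Top2a at least 4.63-fold (adjusted p = 0.034). Large rises included the mitotic kinase Pbk (at least 6.61-fold), the cell division gene Cdca3 (9.57-fold) and H2-Oa, of class II antigen loading (at least 2.75-fold). The largest falls were in the receptor gene Mrgprg (-2.51 ± 0.49), the glutathione transferase Gsta3 (-2.32 ± 0.43), the clock repressor Cry1 (-2.31 ± 0.46), the transcription factor Camta1 (-2.25 ± 0.42), the secreted protein gene Angptl7 (-2.14 ± 0.50) and the glutamate transporter Slc1a1 (at least 2.41-fold lower). Among 20 macrophage markers the fractalkine receptor Cx3cr1 alone passed (6.28-fold higher, adjusted p = 0.032), and among 11 neutrophil markers the elastase Elane alone (1.59-fold, adjusted p = 0.030). Of the 10 fits that left out 1 array, the calls of Mki67, Ccnb1 and Top2a were lost in 7, those of Cx3cr1, Ctsk and H2-Oa in 6, Elane in 5, Slc1a1 in 4, Mmp2 in 2 and Angptl7 in 1.

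In total 448 genes were higher and 342 lower in WT intact (281 and 318 with normexp background correction). As lists, collagen (median 0.56, adjusted p = 7.3e-09), elastic fibre (0.47, 5.6e-06), proteases (0.39, 0.0011), cell cycle (1.70, 1.5e-07), macrophage (0.44, 0.0011), neutrophil (0.67, 0.029) and Schwann and nerve markers (0.32, 0.039) moved up, and smooth muscle contractile genes down (-0.30, 0.015) with no single member passing. The elastic fibre call held (adjusted p = 0.027 with an estimated correlation), and the other 7 were lost, in the same order with adjusted p = 0.22, 0.44, 0.65, 0.74, 0.74, 0.22 and 0.74 with an estimated correlation. Within scan day 3 the count was 1007, the collagen median 0.52 and the cell cycle median 1.58, whereas with slide as a block, where slide 6 alone holds both groups, limma called 0 genes (2644 had an unadjusted p under 0.05) and the medians were 0.39 and 2.04. The count was 346, 355 or 345 without WT control replicate 1, 2 or 3, and 326 without WT intact replicate 6, which stood apart (smooth muscle list mean 4.89 against 5.72 to 6.00 on the others).

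**Figure D2:**
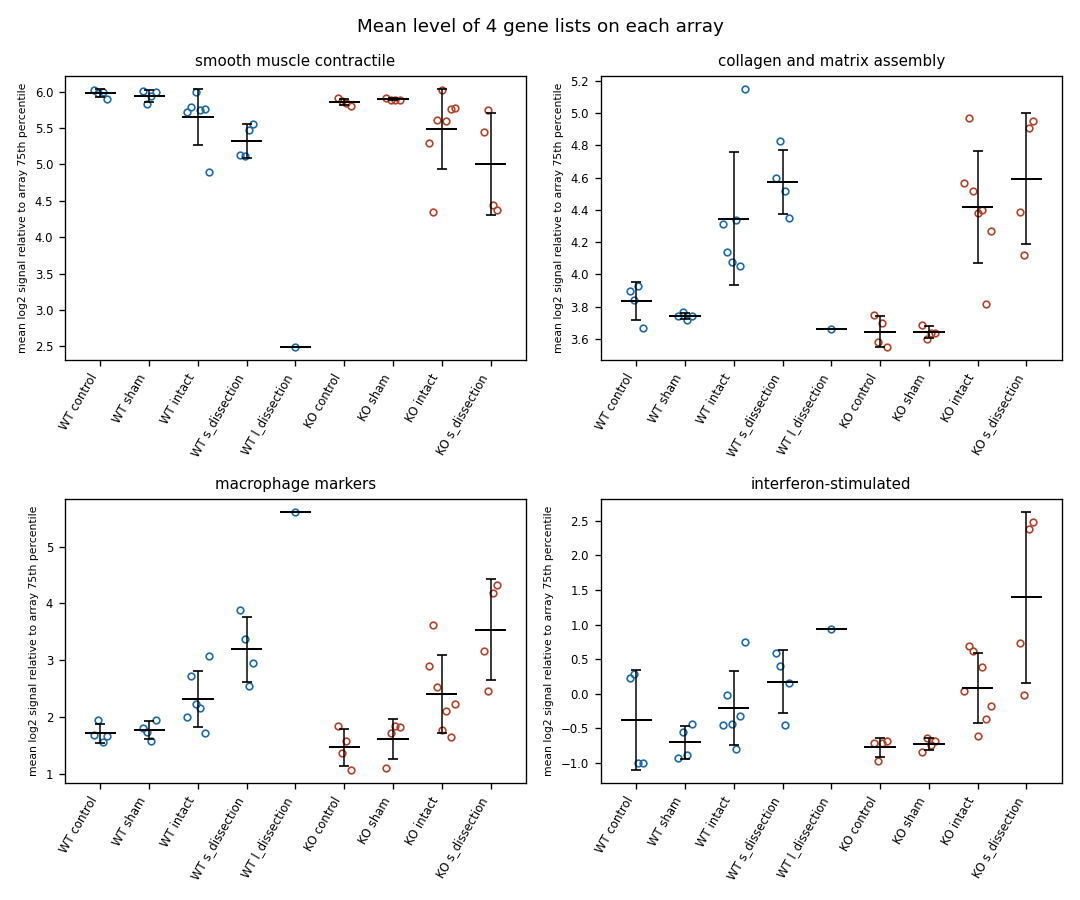
Mean log2 signal, relative to the array's 75th percentile, over the members of the smooth muscle contractile, collagen, macrophage and interferon lists on each array, by group (points are arrays, bars are group means with SD error bars, blue WT, red KO). The smooth muscle mean is 5.98 in WT control, 5.32 in WT s_dissection and 2.49 on the WT l_dissection array, and the macrophage mean is 1.71, 3.19 and 5.61.

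WT aorta with focal disruption (WT s_dissection, n = 4) was set against WT control (n = 4). Smooth muscle genes fell and macrophage genes rose. Of 17 contractile genes 6 fell and 11 did not pass (the same numbers adjusted over the list alone), with the smooth muscle coactivator Myocd 3.46-fold lower (-1.79 ± 0.45, adjusted p = 0.0045) and desmin, Des, 2.17-fold lower. Of 20 macrophage markers 16 rose and 4 did not pass (17 adjusted over the list alone). Cx3cr1 rose 21.3-fold (from -2.34 ± 0.36 to 2.07 ± 0.53, adjusted p = 0.00025), the lipid-sensing receptor Trem2 4.72-fold and lysozyme Lyz1 2.51-fold. Neutrophil markers rose in 5 of 11, among them S100a9 and S100a8, the subunits of calprotectin, 60.7-fold and 29.3-fold (adjusted p = 0.0012 and 0.0043), each well above background on 1 of 4 WT control arrays. Of 15 T and B cell markers 3 rose and 12 did not pass (9 rose and 1 fell adjusted over the list alone), Cd3e of the T cell receptor complex by 0.96 ± 0.19.

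Matrix and cytokine genes moved in the same aortas. Eln rose 6.49-fold (adjusted p = 3.6e-05), Mfap2 5.21-fold, and fibrillin, Fbn1, 2.29-fold, with 10 of 18 elastic fibre genes higher and 8 not passing (11 adjusted over the list alone). Col3a1 rose 2.97-fold (adjusted p = 1.4e-05) and Col1a1 2.92-fold, and of 23 collagen genes 11 rose, 1 fell and 11 did not pass (15 rose and 1 fell adjusted over the list alone). In the list of proteases and inhibitors 12 of 21 rose, 1 fell and 8 did not pass (14 and 1 adjusted over the list alone). An inhibitor among them, Timp1, rose 9.32-fold (adjusted p = 0.00039), and the protease Adamts1 fell by 1.64 on the log2 scale (adjusted p = 0.0016). Of 20 inflammatory cytokine and chemokine genes 11 rose, 1 fell and 8 did not pass (12 and 1 adjusted over the list alone). The interleukin gene Il1b, well above background on 1 of 4 WT control arrays, rose 17.0-fold and the monocyte chemoattractants Ccl2 and Ccl8 8.74-fold and 8.22-fold, while the growth factor Csf1 fell (-0.52 ± 0.12). Among 20 interleukin-6 family and STAT3 target genes 6 rose, including the kinase Pim1 (3.13-fold) and lipocalin Lcn2 (8.46-fold), 2 fell, the shared receptor Il6st (-0.37 ± 0.10) and the factor Cebpd (-1.13 ± 0.23), and 12 did not pass. That list as a whole did not pass (adjusted p = 0.077).

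Cell cycle genes rose in 17 of 23 (18 rose and 1 fell adjusted over the list alone), for example the ubiquitin enzyme Ube2c 13.8-fold and cyclin Ccna2 12.6-fold. Large rises were in osteopontin, Spp1 (at least 63.5-fold, adjusted p = 0.0014; chromosome 5, 104868502 to 104868561), the acute phase gene Saa3 (at least 40.4-fold, adjusted p = 0.014), S100a9, S100a8 and Pbk (at least 15.7-fold). Large falls were in the heat shock gene Hspa1a (-3.33 ± 1.01), Mrgprg (-2.97 ± 0.53), Angptl7 (-2.88 ± 0.54) and Cry1 (at least 1.95-fold lower).

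In this comparison 3069 genes were higher and 3002 lower (3111 and 3507 with quantile normalization, 1118 and 597 at 2-fold or more). The lists passed with medians of -0.54 for smooth muscle (adjusted p = 0.0050), 0.70 for collagen (1.8e-06), 0.59 for elastic fibre (0.00038), 1.06 for proteases (0.00038), 1.49 for inflammatory genes (0.00018), 2.78 for cell cycle (3.2e-08), 1.35 for macrophage (1.1e-07), 1.06 for neutrophil (0.011) and 1.14 for T and B cell markers (0.0038). None held otherwise, with adjusted p = 0.54 for smooth muscle, 0.19 for elastic fibre and 0.47 for the other lists with an estimated correlation. Within scan day 3 the count was 3976 and the smooth muscle and macrophage medians -0.53 and 1.18, and with slide as a block they were 3061, -0.73 and 1.43. Without WT s_dissection replicate 1, whose 75th percentile of signal was 136 (265 to 281 in the rest of its group), the count was 3692. The call of Des was lost in 3 and that of Hspa1a in 1 of the 8 fits that left out 1 array.

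Disrupted and intact stressed WT aorta were compared directly (WT s_dissection, n = 4, against WT intact, n = 6). The myeloid transcription factor Spi1 was 5.29-fold higher in the disrupted aortas (adjusted p = 0.037), the platelet-activating factor receptor Ptafr 2.94-fold and the myeloid lectin Cd33 2.08-fold. Complement C6 (at least 1.72-fold) and the zinc finger gene Zbed3 (2.51-fold) rose too. The largest falls were in the actin-binding gene Klhl1 (-1.47 ± 0.34), the ephrin receptor Epha7 (-1.18 ± 0.26), the growth factor receptor inhibitor Errfi1 (-1.11 ± 0.28) and the kinase Lmtk2 (-1.09 ± 0.21). Of 15 T and B cell markers Cd3e alone rose (1.60-fold, adjusted p = 0.036), and no macrophage (20), inflammatory (20) or cell cycle gene (23) passed alone, although adjusted over the list alone 2 macrophage and 1 inflammatory gene did. Each of the 13 called genes that met the naming rule lost its call in at least 1 of the 10 fits that left out 1 array, Ptafr in 8, Spi1 and Errfi1 in 6, and Cd33 and Cd3e in 4.

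A total of 293 genes were higher and 288 lower (348 and 416 with quantile normalization, 20 and 54 at 2-fold or more). The lists that moved up were macrophage (median 0.88, adjusted p = 1.5e-06), inflammatory (1.06, 6.5e-05), cell cycle (1.00, 0.00015), T and B cell (0.68, 0.0070), protease (0.32, 0.043) and alternatively activated macrophage (0.51, 0.043), each with adjusted p = 0.66 with an estimated correlation. Within scan day 3 limma called 2 genes and within slide 2 it called 0 (1249 had an unadjusted p under 0.05), with list medians in that scan day of 0.58 for macrophage and 0.68 for inflammatory genes. Slide as a block gave 126 genes and medians of 0.91 and 1.02. The count was 0 without WT s_dissection replicate 1 (2489 genes had an unadjusted p under 0.05), 300, 2069 and 895 without replicates 2, 3 and 4, and 81, 207 and 209 without WT intact replicates 1, 2 and 5.

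The lone WT l_dissection array has no replicate, so its values were set beside the WT control mean with no test. Arginase, Arg1, was at least 2366-fold higher (7.20 against -6.05 ± 0.29), Spp1 at least 1116-fold and the neutrophil gene Retnlg at least 833.5-fold. S100a9, S100a8 and the chitinase-like gene Chil3 lay at 9.27, 8.37 and 5.51 against control means of -3.90, -4.09 and -5.05, and each was well above background on 1 of 4 WT control arrays. Below the control mean lay the methyltransferase Inmt (-8.39), Camta1 (at least 22.1-fold lower), Fbxo40 (at least 24.3-fold) and the muscle gene Tcap (-6.31). Of 17 smooth muscle genes 16 lay below the range of the other 37 arrays, with Myocd at -4.87 and the myosin Myh11 at -4.61, and 18 of 20 macrophage markers lay above it. Il6, well above background on 1 of 4 WT control arrays, was 8.03 higher, Cxcl5 at least 322.6-fold and the metalloproteinase Mmp9 at least 212.3-fold.

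Among the 9271 genes outside the range of the other arrays (4359 above, 4912 below), 6414 also differed at least 2-fold from the WT control mean (3042 higher, 3372 lower). List medians, with their percentile among 10000 random lists of equal size and mean level as a description of these libraries, were -3.60 for smooth muscle (percentile 0), -1.13 for elastic fibre (0.11), -0.41 for collagen (2.41), 2.05 for proteases, 3.37 for the interleukin-6 list, 4.03 for inflammatory genes, 4.25 for cell cycle, 4.07 for macrophage, 5.75 for neutrophil and 4.16 for T and B cell markers (percentile 100 for each of these 7), and 0.82 for interferon-stimulated genes (99.92). Members above the range of the other arrays numbered 8 of 21 for proteases (6 lay below it), 13 of 20 for the interleukin-6 list (1 below), 13 of 20 for inflammatory genes, 5 of 23 for cell cycle, 7 of 11 for neutrophil and 10 of 15 for T and B cell markers. Of 20 interferon-stimulated genes 0 lay above it and 1 below. With normexp background correction 4052 genes lay outside the range by 2-fold.

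WT sham aorta was compared with WT control (n = 4 each). Akap5, a kinase anchoring protein gene, rose 4.58-fold (2.20 ± 0.50, adjusted p = 0.049), the repressor Bcl6 3.54-fold and the synaptotagmin Syt15 3.17-fold. Mrgprg fell by 3.03 ± 0.53 on the log2 scale (adjusted p = 0.012), Cry1 was at least 2.21-fold lower and the glucocorticoid-induced gene Tsc22d3 3.48-fold lower. Of the 8 fits that left out 1 array, the call of Akap5 was lost in all 8, those of Bcl6, Syt15 and Tsc22d3 in 7, and those of Cry1 and Mrgprg in 3. Both called lists, red cell and platelet markers (10 measured, median 0.76, adjusted p = 0.0065) and immediate early and heat shock genes (13 measured, median 0.25, adjusted p = 0.027), moved up with no member passing (1 red cell and platelet gene adjusted over the list alone), each with adjusted p = 0.82 with an estimated correlation. Red cell and platelet markers averaged 1.05 on WT sham replicate 2 and -0.78 to -0.68 on the other WT sham arrays. In total 19 genes were higher and 44 lower. Within scan day 3, which for these groups is slide 1, limma called 5 genes in a fit of the arrays of that day and 13 in a fit of slide 1 alone, with red cell and immediate early medians of 0.95 and 0.45. Slide as a block gave 91 genes and medians of 0.76 and 0.25. Leaving out any array but WT sham replicate 4 gave 2 to 21 genes.

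Intact stressed WT aorta was also set against WT sham (n = 6 and 4). Col3a1 rose 2.07-fold (adjusted p = 0.0029), Col1a1 2.04-fold and fibronectin, Fn1, 1.54-fold, the 3 of 23 collagen genes that passed (9 adjusted over the list alone), and Mfap4 rose 2.24-fold as the sole elastic fibre gene of 18 (6 adjusted over the list alone). The signal regulatory gene Sirpb1b was at least 7.96-fold higher and the mitotic gene Ckap2 6.06-fold. Spata5l1 (-1.20 ± 0.26), the GTPase Rrad (-1.11 ± 0.24) and the endonuclease subunit Eme2 (-0.41 ± 0.09) fell most. No cell cycle gene of 23 passed over all genes and 15 did adjusted over the list alone. The count was 106 higher and 5 lower. Collagen (median 0.55, adjusted p = 1.9e-12), elastic fibre (0.38, 0.00035) and cell cycle lists (1.51, 1.9e-09) moved up with adjusted p = 0.12, 0.12 and 0.55 with an estimated correlation. So did proteases, inflammatory, interferon-stimulated, macrophage and neutrophil lists (adjusted p = 0.017, 0.019, 0.045, 0.00096 and 0.016, and 0.55, 0.69, 0.71, 0.58 and 0.55 as adjusted p with an estimated correlation). Smooth muscle, fatty acid oxidation and red cell lists moved down (adjusted p = 0.0047, 0.019 and 0.023, and adjusted p = 0.62, 0.55 and 0.55 with an estimated correlation). Within scan day 3 there were 206 genes and collagen and cell cycle medians of 0.59 and 1.34. Slide as a block, through slide 6, gave 2 genes and 0.49 and 1.85. Counts were 32 to 60 without a WT sham array, and 219, 73 and 38 without WT intact replicates 1, 3 and 6. Col3a1 and Fn1 kept their call in each of these 10 fits, whereas Mfap4 and Eme2 lost it in 7, Ckap2 and Rrad in 6, Sirpb1b and Spata5l1 in 5, and Col1a1 in 2.

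In KO aorta the same comparison (KO intact, n = 7, against KO sham, n = 4) gave 296 genes higher and 99 lower. Of 23 cell cycle genes 13 rose and 10 did not pass (20 adjusted over the list alone), Mki67 7.24-fold and the checkpoint kinase Bub1 at least 3.71-fold. Of 23 collagen genes 8 rose and 15 did not pass (19 adjusted over the list alone), Col3a1 2.25-fold and Loxl2 2.69-fold, and of 18 elastic fibre genes 4 rose and 14 did not pass (10 adjusted over the list alone), Eln 4.28-fold and lysyl oxidase, Lox, 2.98-fold. The largest rises were in the kinase Melk (at least 7.17-fold), Iqgap3 (14.4-fold) and Pbk (11.4-fold), and the largest falls in Fam78b (-1.71 ± 0.30) and Smim5 (-1.18 ± 0.29). Collagen (median 0.67, adjusted p = 3.2e-17) and elastic fibre lists (0.45, 6.3e-06) held with adjusted p = 0.037 and 0.031 with an estimated correlation, and the cell cycle list (2.50, 8.4e-21) did not, with adjusted p = 0.15 with an estimated correlation. Proteases, inflammatory, interferon-stimulated, macrophage, neutrophil, T and B cell and red cell lists also moved up and smooth muscle genes down, with adjusted p from 4.4e-06 to 0.024 and from 0.36 to 0.46 with an estimated correlation. Within slide 4 limma called 43 genes, within scan day 1 it called 0 (2745 had an unadjusted p under 0.05) with collagen and cell cycle medians of 0.66 and 2.35. Slide as a block gave 615 genes, 0.84 and 2.98. Counts were 197, 63, 98 and 205 without KO sham replicates 1 to 4, and 164, 164, 232, 263 and 1301 without KO intact replicates 1, 2, 3, 5 and 6. Of these 11 fits Smim5 lost its call in 7, Lox in 5, and Mki67, Bub1, Loxl2 and Pbk in 1.

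KO groups were also set against WT control, as the series design states, which mixes genotype with intervention and, but for slide 6, with scan day. In KO intact (n = 7) 17 of 23 cell cycle genes rose and 6 did not pass (18 adjusted over the list alone), Mki67 8.35-fold and Ccnb1 by 3.46 ± 0.67 on the log2 scale. Of 23 collagen genes 8 rose and 15 did not pass (11 rose and 1 fell adjusted over the list alone), Col3a1 2.33-fold and Col1a1 2.30-fold. Of 18 elastic fibre genes 6 rose and 12 did not pass (7 rose and 1 fell adjusted over the list alone), Eln 4.45-fold. Of 20 macrophage markers 4 rose (4 adjusted over the list alone), Cx3cr1 8.32-fold and the surface receptor Adgre1 2.45-fold, and 1 of 17 smooth muscle genes, the myosin light chain Myl9, fell (-0.51 ± 0.16, adjusted p = 0.032, a call lost in 4 of the 11 fits that left out 1 array; 4 adjusted over the list alone). The largest changes were in Shcbp1 (at least 11.1-fold higher), Pbk (at least 12.9-fold), Iqgap3 (18.6-fold), Gsta3 (-2.33 ± 0.42), the clock gene Per2 (-2.24 ± 0.61) and Camta1 (-2.17 ± 0.40).

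In KO intact 1830 genes were higher and 1652 lower than in WT control (1803 and 2285 with normexp background correction). Cell cycle (median 2.44, adjusted p = 2.5e-13), collagen (0.36, 5.7e-06), elastic fibre (0.34, 0.0012), proteases (0.63, 0.0014), inflammatory (0.98, 0.012) and macrophage lists (0.61, 0.0028) moved up and smooth muscle genes down (-0.51, 0.0014), in that order with adjusted p = 0.45, 0.45, 0.24, 0.49, 0.68, 0.68 and 0.68 with an estimated correlation. With slide or scan day as a block 6 or 7 genes passed, and the medians were 3.15 or 2.14 for cell cycle, 0.56 or 0.47 for collagen and 0.30 or -0.02 for macrophage genes. The count was 1834, 1612 and 2097 without WT control replicates 2, 3 and 4.

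In KO s_dissection (n = 4) 13 of 17 smooth muscle genes fell and 4 did not pass (14 adjusted over the list alone), calponin, Cnn1, by 1.09 ± 0.25 and Myocd by 1.83 ± 0.45 on the log2 scale. Of 20 macrophage markers 17 rose and 3 did not pass (17 adjusted over the list alone), Cx3cr1 29.3-fold and Ms4a7 12.1-fold. Of 20 interferon-stimulated genes 16 rose and 4 did not pass (18 adjusted over the list alone), Mx1, an antiviral GTPase, 21.3-fold (adjusted p = 0.00068) and Isg15 4.54-fold. Of 20 inflammatory genes 16 rose, 1 fell and 3 did not pass (17 and 1 adjusted over the list alone), Il1b 55.9-fold and Ccl8 32.6-fold. Of 20 interleukin-6 family and STAT3 target genes 10 rose, 1 fell and 9 did not pass (11 and 2 adjusted over the list alone), the receptors Il21r at least 6.04-fold and Il4ra 6.85-fold. Cell cycle genes rose in 20 of 23 (20 adjusted over the list alone), Mki67 14.1-fold. The largest changes were in Saa3 (at least 152.6-fold higher), Spp1 (at least 118.4-fold), S100a9 (208-fold, well above background on 1 of 4 WT control arrays, as was Il1b), Tmem52 and Tmem200b (at least 3.62-fold and 2.19-fold lower) and Camta1 (-2.78 ± 0.46).

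In this comparison 3009 genes were higher and 3321 lower (3423 and 3302 with quantile normalization, 1650 and 773 at 2-fold or more). Lists passed for cell cycle (median 3.17, adjusted p = 9.3e-14), macrophage (1.75, 2.1e-10), interferon-stimulated (1.85, 7.5e-10), inflammatory (2.50, 3.0e-10), interleukin-6 (1.33, 0.00033), smooth muscle (-1.01, 3.1e-06), proteases (1.41, 3.1e-06), T and B cell (1.75, 3.2e-06), neutrophil (2.55, 1.0e-05), collagen (0.62, 3.9e-05), alternatively activated macrophage (1.17, 0.0022) and elastic fibre genes (0.33, 0.020), and none held, with adjusted p = 0.19 to 0.23 with an estimated correlation. With slide as a block 3 genes passed and with scan day 88, and the medians were 1.81 and 1.16 for macrophage, 2.0 and 1.46 for interferon-stimulated and -1.60 and -1.09 for smooth muscle genes. The count was 4006 and 3471 without KO s_dissection replicates 3 and 4.

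KO sham (n = 4) against WT control gave 99 genes higher and 82 lower. The ubiquitin ligase Trim6 rose 4.06-fold (adjusted p = 0.040) and Slitrk6 3.86-fold. The chaperone Hsph1 fell (-2.52 ± 0.48, adjusted p = 0.010), as did the sarcomere gene Myoz2 (-1.92 ± 0.34), and Slc1a1 was at least 2.83-fold lower. None of the 26 lists passed. Slide or scan day as a block gave 6 or 8 genes. Counts were 329, 3 and 57 without WT control replicates 1, 2 and 3, and 45 to 91 without a KO sham array. Of these 8 fits Trim6 and Slitrk6 lost their call in 6, Slc1a1 in 3, and Hsph1 and Myoz2 in 1.

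The genotypes were compared first without intervention (KO control against WT control, n = 4 each). The 1 gene that met the naming rule was Rasal2, of Ras regulation, lower in KO by 0.71 ± 0.13 (adjusted p = 0.050 after rounding). The other called gene, named here after its values were seen, was the hormone subunit gene Cga, with a mean of -2.02 in KO control and -5.56 in WT control (adjusted p = 0.050 after rounding), well above background on 3 of 4 KO control arrays and on no WT control array. As lists, red cell and platelet markers (10 measured, median 0.98, adjusted p = 3.4e-05) and immediate early and heat shock genes (13 measured, 0.42, 0.014) were higher, and white adipocyte (9 measured, -0.90, 0.0089), interferon-stimulated (20 measured, -0.40, 0.016) and fatty acid oxidation genes (14 measured, -0.13, 0.039) lower. No member passed over all genes, and adjusted over the list alone 1 fatty acid oxidation gene rose and 2 fell. None of the 5 held, with adjusted p = 0.31 for the red cell list, 0.93 for interferon and 0.85 for the others with an estimated correlation. Slide as a block, through slide 6, gave 21 genes and medians of 1.76, -0.32, -0.76, -0.49 and -0.25 in that order of lists, and scan day 3, where the genotypes lay on different slides, 2 genes and 0.92, 0.41, -1.12, -0.17 and -0.12. Leaving out any array gave 0 or 1 genes, and Rasal2 was called in none of these 8 fits.

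After sham (KO sham against WT sham, n = 4 each) KO aorta had 33 genes higher and 3 lower. The transcription factor Tbx22 was 3.59-fold higher (1.84 ± 0.31, adjusted p = 0.011), the natural killer receptor Klra1 3.26-fold, the kinase Sik1 by 1.59 ± 0.31 on the log2 scale, the deubiquitinase Usp2 2.70-fold and the pheromone receptor gene Vmn1r204 2.29-fold. The 3 lower genes that met the naming rule were Tspo2 (-0.88 ± 0.18), Lyplal1 (-0.68 ± 0.14) and Eme2 (-0.50 ± 0.10). Red cell and platelet markers (10 measured, none passing over all genes, 3 lower adjusted over the list alone) were lower as a list (median -0.90, adjusted p = 0.0020, and adjusted p = 0.95 with an estimated correlation). Slide or scan day as a block, which compared 1 array per genotype on slide 6, gave 8 or 7 genes and medians of -0.20 or -0.50. The count was 0, 5 and 15 without WT sham replicates 2, 3 and 4, 206 without KO sham replicate 1 and 0 without replicate 2, 3 or 4 (1820 to 1967 genes had an unadjusted p under 0.05 in the fits with none called). Each named call was lost in 4 to 7 of these 8 fits.

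Under stress without a lesion (KO intact, n = 7, against WT intact, n = 6) 572 genes were higher in KO and 831 lower (28 and 444 at 2-fold or more). Of 23 cell cycle genes 1 passed, the replication clamp Pcna, 1.43-fold higher (4.21 ± 0.41 against 3.69 ± 0.18, adjusted p = 0.027; 1 adjusted over the list alone), and the list was higher (median 0.83, adjusted p = 3.7e-05, and adjusted p = 0.94 with an estimated correlation). The highest genes were the olfactory receptor genes Olfr332 (1.58 ± 0.35) and Olfr1349 (2.34-fold), complement C6 (at least 1.52-fold), Klra1 (2.27-fold), the dehydrogenase-like Mdh1b (1.97-fold) and the peptide receptor Glp2r (1.81-fold). The lowest were Ccdc158 (at least 2.44-fold lower), Pdzd7 (-1.97 ± 0.51), the pheromone receptor gene Vmn2r10 (-1.73 ± 0.36), Arhgap33os (-1.73 ± 0.37) and the keratin-associated Krtap12-1 (-1.68 ± 0.44). No list of macrophage, collagen, smooth muscle or interferon genes passed. With slide or scan day as a block 4 or 1 genes passed and the cell cycle median was 0.78 or 0.35. Both blocks turned the sign of Klra1 and Krtap12-1, slide that of Mdh1b, and scan day that of Olfr332, Vmn2r10 and Arhgap33os. Either block tied the KO to the WT arrays through KO sham replicate 1 alone, so why these signs turned cannot be told. The count was 878 without KO intact replicate 1. Of the 13 fits that left out 1 array Glp2r lost its call in 8, Pcna in 5 and Olfr1349 in 1.

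In disrupted aorta (KO s_dissection against WT s_dissection, n = 4 each) 6 of 20 interferon-stimulated genes were higher in KO and 14 did not pass (15 were higher adjusted over the list alone). An exact permutation test of the list's array means, two-sided, gave p = 0.17, where 0.029 is the smallest p that 4 against 4 arrays allow, and the list's call was lost with adjusted p = 0.85 with an estimated correlation. The viral RNA sensor Ifih1 rose 2.04-fold (1.03 ± 0.24, adjusted p = 0.0076), Ifit2 2.06-fold, the guanylate-binding gene Gbp3 2.46-fold and the ISG15 protease Usp18 3.05-fold. Of 20 inflammatory genes the chemokine Cxcl16 rose 2.33-fold (adjusted p = 0.024; 1 adjusted over the list alone). Of 17 smooth muscle genes 3 were lower and 14 did not pass (3 adjusted over the list alone), smooth muscle actin Acta2 (-0.64 ± 0.17, adjusted p = 0.014), Tagln (-0.65 ± 0.15) and Myl9 (-0.72 ± 0.18). Of 23 collagen genes 5 were lower and 18 did not pass (5 adjusted over the list alone), among them Bgn (-0.80 ± 0.14), Col6a2 (-0.69 ± 0.14) and Sparc (-0.57 ± 0.14). Without WT s_dissection replicate 1 these differences were -0.41 for Acta2, -0.51 for Myl9 and -0.36 for Sparc, none of them called, and -0.45 for Tagln, -0.53 for Col6a2 and -0.88 for Bgn. Neither list passed (medians -0.46 and -0.02, adjusted p = 0.069 and 0.48), and with slide as a block the collagen list was higher in KO (median 0.44, adjusted p = 0.030). Of 9 brown adipocyte markers the coactivator Ppargc1a fell (-1.11 ± 0.33, adjusted p = 0.027; 4 fell adjusted over the list alone).

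The highest single genes were Tmem255a (at least 2.75-fold), the transporter Slco6b1 (2.08 ± 0.52, with normexp background correction -0.03), Tmem144 (4.10-fold), Nwd2 (at least 2.08-fold) and Klra1 (3.45-fold). The lowest were Zbed3 (-2.75 ± 0.30, adjusted p = 3.9e-06; chromosome 13, 96106826 to 96106885), the TWEAK receptor Tnfrsf12a (-2.22 ± 0.44), the hedgehog receptor Ptch1 (-1.80 ± 0.37), Cutal (-1.63 ± 0.33) and the host gene of microRNA 22, Mir22hg (-1.47 ± 0.14). In total 1014 genes were higher in KO and 1538 lower (227 and 150 at 2-fold or more).

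The interferon list passed (median 1.34, adjusted p = 1.1e-08), as did the inflammatory list (1.06, 0.0031) and, lower in KO, brown adipocyte markers (-0.89, 0.028), each with adjusted p = 0.85 with an estimated correlation. The interferon list mean was 1.39 ± 1.24 in KO and 0.17 ± 0.45 in WT s_dissection. Brown adipocyte markers averaged 0.62 and 1.11 on WT s_dissection replicates 1 and 2 against -0.37 and -0.39 on replicates 3 and 4, and -0.88 to -0.57 on the KO s_dissection arrays. Slide or scan day as a block left 5 or 7 genes, with medians of 1.46 or 0.95 for interferon, 2.33 or 1.33 for inflammatory and -1.01 or -0.93 for brown adipocyte genes. A fit of these 8 arrays alone called 0 genes (3179 had an unadjusted p under 0.05), against 2552 with the variance estimated over all 38. The count was 1022 without WT s_dissection replicate 1, and 4042, 1152 and 867 without KO s_dissection replicates 2, 3 and 4. Of the 8 fits that left out 1 array, Usp18 lost its call in 4, Gbp3, Cxcl16, Ppargc1a and Myl9 in 3, Acta2 in 2, and Ifih1, Sparc, Tmem144 and Nwd2 in 1.

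Within KO aorta, disruption was compared with no lesion (KO s_dissection, n = 4, against KO intact, n = 7), with 351 genes higher and 103 lower. Of 20 interferon-stimulated genes 4 rose and 16 did not pass (19 adjusted over the list alone), the chemokine Cxcl9 5.09-fold (adjusted p = 0.039) and the oligoadenylate synthetase Oas1a 3.54-fold. Of 20 inflammatory genes 5 rose and 15 did not pass (16 adjusted over the list alone), Tnf 4.19-fold and the neutrophil chemokine Cxcl5 25.4-fold, the latter with an SD of 4.60 between KO s_dissection arrays. Of 20 macrophage markers 3 rose (17 adjusted over the list alone), Aif1 3.63-fold, the Fc receptor Fcgr1 4.22-fold and Cd68 2.94-fold. Of 11 neutrophil markers 3 rose (8 adjusted over the list alone), with the chemokine receptor Cxcr2 7.26-fold higher, and of 15 T and B cell markers 6 rose (8 adjusted over the list alone), with Cd3d 6.42-fold and the kinase Lck 3.12-fold higher. Other large rises were in Klk1b24 (5.08-fold) and Stfa2 (4.11-fold). The largest falls were in Mroh1 (-1.09 ± 0.24), the growth factor homologue Fgf13 (-1.02 ± 0.22), the methyltransferase Kmt2a (-0.91 ± 0.23) and Gnb4 (-0.79 ± 0.14).

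The lists that moved up were interferon (median 1.37, adjusted p = 2.9e-16), inflammatory (2.07, 1.9e-14), macrophage (1.02, 2.5e-13), neutrophil (2.86, 1.3e-08), T and B cell (1.17, 4.0e-07), interleukin-6 (0.65, 5.0e-05), protease (0.46, 0.00016), cell cycle (0.60, 0.00057) and alternatively activated macrophage (0.36, 0.011), and smooth muscle genes moved down (-0.48, 0.00023) with no member passing. None held, with adjusted p between 0.14 and 0.62 with an estimated correlation. All arrays of both groups were scanned on day 1. A limma fit of that day's arrays alone called 6 genes, within slide 5 it called 0 (1656 had an unadjusted p under 0.05), and slide as a block gave 3 genes and interferon and macrophage medians of 1.82 and 1.44. Limma called 0 genes without KO s_dissection replicate 3 (2478 had an unadjusted p under 0.05) and 3 without replicate 4. Counts were 66 to 2966 without any other array. Each of the 29 called genes that met the naming rule lost its call in 2 or more of these 11 fits.

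Averaged over control, sham, intact and s_dissection (19 KO and 18 WT arrays), 711 genes were higher in KO and 869 lower (1013 and 832 with quantile normalization, 9 and 53 at 2-fold or more). Lyz2, a lysozyme gene of macrophages and neutrophils (chromosome 10, 116719175 to 116719234), was lowest, by 1.49 ± 0.40 on the log2 scale (adjusted p = 0.024), and by 1.05 ± 0.17 (adjusted p = 0.00059) without KO sham replicate 1, where it was not well above background. Of 20 macrophage markers Lyz2, Lyz1 (-0.55 ± 0.16) and the integrin Itgam (-0.30 ± 0.09, but 0.19 as the mean of its probes) were lower and the list did not pass (median 0.15, adjusted p = 0.81), but with scan day as a block its median was -0.35 (adjusted p = 0.0079, over its alternatives 0.0079 to 0.98). Of 17 smooth muscle genes 3 were lower, Acta2 (-0.32 ± 0.08), Tagln (-0.30 ± 0.07, but 0.00 in the submitters' quantile-normalized values) and Myl9 (-0.36 ± 0.09), with 4 adjusted over the list alone. Of the collagen genes Bgn (-0.36 ± 0.07), Sparc (-0.33 ± 0.07), Col6a2 (-0.31 ± 0.07) and Col1a2 (-0.40 ± 0.09) were lower and that list did not pass. Higher in KO were Ccl8 (2.70-fold, adjusted p = 0.015), Nxpe5 (2.29-fold), the helicase Ddx25 (1.00 ± 0.17), the NAD glycohydrolase Cd38 (1.83-fold), the transcription factor Gcm1 (1.65-fold) and the endothelin receptor Ednrb (1.61-fold), and of 20 interferon-stimulated genes Ifih1 (1.29-fold, adjusted p = 0.049; 2 adjusted over the list alone). After Lyz2 the lowest were Rsph4a (-0.72 ± 0.20), Cutal (-0.68 ± 0.16), Atf7 (-0.67 ± 0.13) and Hsf4 (-0.67 ± 0.12).

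Smooth muscle genes as a list were lower in KO (median -0.18, adjusted p = 0.040), and inflammatory (0.43), interferon (0.34) and cell cycle genes (0.27) higher (adjusted p = 0.010 each), all 4 with adjusted p = 0.87 with an estimated correlation. Inflammatory members passed in 1 of 20 (2 adjusted over the list alone), and no cell cycle gene did. Slide or scan day as a block left 6 or 4 genes, list medians of -0.36 or -0.15, 0.72 or 0.55, 0.20 or 0.05 and 0.64 or -0.02 in that order, Ednrb at -0.64 or -0.26, Ifih1 at -0.04 or -0.03, and Rsph4a at 0.01 with slide. The count was 971 without WT control replicate 2. Of the 37 fits that left out 1 array Ifih1 lost its call in 26, Ednrb in 12, Itgam in 10 and Lyz1 in 1.

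Whether the response to stress differed by genotype was tested as an interaction (intact minus control, KO minus WT, 11 and 10 arrays). The difference was positive for 108 genes and negative for 106 (19 and 28 with quantile normalization), and at 2-fold or more for 5 and 79. The helicase Ddx23 (1.26 ± 0.31, adjusted p = 0.043), the receptor Adgrg2 (1.15 ± 0.21, adjusted p = 0.014) and the ribonuclease subunit Rpp30 (0.95 ± 0.17) had the largest positive differences, and the pheromone receptor gene Vmn1r197 (-2.68 ± 0.64), Arhgap33os (-2.63 ± 0.59) and Plaat5 (-2.56 ± 0.62) the largest negative ones. For Socs3 it was -0.04 ± 0.58 (adjusted p = 0.98). Interferon-stimulated (20, median 0.56), cell cycle (23, 0.69) and fatty acid oxidation lists (14, 0.24) were positive. These had adjusted p = 0.014, 0.014 and 0.050 (under the threshold unrounded), and 0.90 each with an estimated correlation. The last list averaged 2.96 and 2.85 in WT control and intact, 2.84 and 2.93 in KO. Interferon averaged -0.38 ± 0.73 and -0.22 in WT, and -0.77 ± 0.14 and 0.08 in KO, so WT control scatter enters the difference. No member passed over all genes, and over the list alone 4 fatty acid oxidation genes were positive. Slide or scan day as a block left 3 or 1 genes and medians of 0.54 or 0.42 for interferon, 0.51 or 0.34 for cell cycle and 0.10 or 0.09 for fatty acid oxidation. The count was 13 without WT control replicate 1, 28 without KO control replicate 4 and 71 to 136 without any of 10 other arrays. Of the 21 fits that left out 1 array Ddx23 lost its call in 15, Plaat5 in 13, Vmn1r197 in 11 and Arhgap33os in 4.

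Lists for TGF-beta pathway, calcification, endothelial, fibroblast, hypoxia and glycolysis, renin-angiotensin, skeletal muscle and sympathoadrenal genes passed in none of the 16 comparisons. Their lowest adjusted p-values were 0.054, 0.12, 0.082, 0.082, 0.50, 0.10, 0.24 and 0.13 in that order.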

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

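Here the exact test of interferon list means and the intact interaction were set before, and the others were chosen after, the result was seen. Single arrays far from their group were sought in 240 groups of values (about 12 by chance), and 15 were found.

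Outside slide 6, KO and WT arrays under stress were scanned on different days, and so were KO and WT sham arrays, so a difference between scan days would appear in sham as well. With slide 6 left out, 2092 genes were called in KO intact against WT intact. Of these 88.4% had the same sign in KO sham minus WT sham (63.4% of all genes did). Scan day or slide 4 (KO sham and 5 KO intact arrays) would give this. Their sign in control was shared by 58.9% (50.7% of all genes). The median gene kept 0.44 of its difference after the sham difference was subtracted (quartiles 0.14 and 0.76). So scan day, slide and genotype with or without stress cannot be told apart for KO intact. A genotype difference shared with sham mice would give the same signs and was not tested.

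For KO s_dissection against WT s_dissection 1147 genes were called without slide 6. In control 37.2% and in sham 71.1% had the same sign (47.6% and 57.6% of all genes). KO control and 1 WT s_dissection array lay on slide 3, so the first share cannot test genotype without stress. The median gene kept 0.78 of its difference after subtraction (quartiles 0.54 and 1.04), as an unrelated sham difference would also leave, and 64 genes were called. With slide 6 kept, 3 of 35 array splits (real one included) called 2552 or more. So genotype with or without stress, slide, scan day and variation between arrays cannot be told apart. The interferon list, 1.38 higher in KO s_dissection without slide 6, was -0.04 in sham, which argues against scan day as its cause, but the exact permutation p of 0.17 (n = 4 and 4) leaves variation between single arrays open. Severity of disruption within a label was not measured.

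Lyz2 was lower in KO in each condition, by 0.93 to 1.12 on the log2 scale with KO sham replicate 1 left out (exact permutation p = 0.029 in control, 0.029 in sham, 0.0087 in intact and 0.11 in s_dissection, adjusted p = 0.038, 0.038, 0.035 and 0.11). The other 18 macrophage markers, without the paralog Lyz1 (-0.55) and all above Lyz2, had a median of 0.17 in the average (SD between markers 0.22), -0.28 with scan day as a block (0.29), -0.02 with slide as a block (0.42) and -0.29 in control on scan day 3 (0.24), and with Lyz1 0.16, -0.31, -0.06 and -0.30, which argues against fewer macrophages as the whole cause and leaves a smaller part open. On scan day 3 the lowest WT control array lay 0.59 above the highest KO control array, which argues against scan day as the whole cause, while slide stays open, since those arrays lay on different slides and WT and KO control read 1.59 and 1.40 on slide 6. The difference nearest to 0 over the 4 conditions was -0.93, near what the loss of 1 of 2 copies would give, so a candidate explanation, a hypothesis found and tested on the same data, is that the construct that deletes Socs3, which the labels do not name, sits in Lyz2. Over the alternatives the average ran from -6.41 to -0.99 (adjusted p = 6.4e-10 to 0.042), where -6.41 came with scan day and -6.13 with slide as a block, which rest mostly on KO sham replicate 1 (-6.07).

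A genotype difference in the response to stress was called for 214 genes in intact against control (1 with scan day as a block). Of these groups KO intact alone lay on day 1. In s_dissection against sham 117 were called (21 positive and 96 negative). Without slide 6 this gave 64, and intact against sham 1. In both most arrays of a genotype shared a day.

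Single arrays set apart follow, with the range of the rest of the group. Lyz2 was -6.07 on KO sham replicate 1 (0.86 to 1.18), where macrophage markers averaged 1.09 (1.71 to 1.83) and smooth muscle genes 5.92 (5.89 to 5.89). The 75th percentile of signal was 136 on WT s_dissection replicate 1 (265 to 281), where fibroblast markers averaged 4.52 (3.72 to 3.82). Smooth muscle averaged 4.89 (5.72 to 6.00) and collagen 5.15 (4.05 to 4.34) on WT intact replicate 6. On WT s_dissection replicate 3 the interleukin-6 list averaged -0.12 (0.95 to 1.12), inflammatory -0.32 (0.96 to 1.19) and neutrophil genes -1.65 (-0.45 to -0.20). Interferon genes averaged -0.98 on KO control replicate 2 (-0.72 to -0.69) and TGF-beta 3.20 on replicate 4 (3.45 to 3.48). Fatty acid oxidation genes averaged 3.06 on KO sham replicate 3 (2.97 to 2.98), Schwann 0.02 on WT control replicate 3 (0.19 to 0.21) and red cell 1.05 on WT sham replicate 2 (-0.78 to -0.68). No pairs were sought, but KO s_dissection replicates 3 and 4 scored 117.3 and 121.6 on component 1 (others 47.1 and -6.4).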

How the results depend on the processing

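The alternatives were fixed before the data were examined except for 4, scan day as a block, fits within 1 scan day, leaving out 3 arrays and subtracting sham, which were chosen after the result was seen. A count is given below only where it moved more than 1.5-fold from that in the results. Beside a count of 0 by limma stands the number of genes at an unadjusted p under 0.05, marked unadjusted. The cause was not tested unless a sentence says so.

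Changes to how the signal was read came first. With normexp background correction (offset 50) the counts of genes called were KO control 1 and WT l_dissection 4052 against WT control, and KO against WT intact 2506, KO against WT s_dissection 4655, WT intact against WT sham 62, KO s_dissection against KO intact 950, the average KO minus WT 4471 and the interaction 379. With no filter on dim probes they were WT sham 19, WT intact 509, KO control 0 (1997 unadjusted) and KO sham 103 against WT control, and KO against WT sham 22, KO against WT intact 2869, KO against WT s_dissection 6362, WT intact against WT sham 70, KO intact against KO sham 217, WT s_dissection against WT intact 216, KO s_dissection against KO intact 235, the average 6315 and the interaction 76. A stricter filter gave KO control 0 (1565 unadjusted) against WT control, and KO against WT sham 58. The mean of a gene's probes in place of 1 probe gave WT sham 35 and KO control 0 (1503 unadjusted) against WT control, and KO against WT sham 12. Quantile normalization gave KO control 4 against WT control, and the interaction 47, and the submitters' series matrix values gave KO control 4 against WT control, and the interaction 46.

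Directions moved too, given as genes higher and lower, and splits given in the results are not repeated. With normexp WT s_dissection against WT intact split into 317 and 164, and the average into 1282 and 3189. Quantile normalization gave 32 and 40 for WT sham against WT control and 1342 and 1356 for KO against WT s_dissection. The series matrix gave 32 and 40 for WT sham against WT control, 1014 and 846 for the average and 18 and 28 for the interaction. With no filter on dim probes the split was 615 and 2254 for KO against WT intact, 1241 and 5121 for KO against WT s_dissection and 1061 and 5254 for the average. Slco6b1, Tagln and Itgam moved as given in the results. The gene list tests called 93 of 416 with the preset correlation and 3 with the estimated one.

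Blocks for slide and scan day moved most counts. Slide as a fixed block gave WT intact 0 (2644 unadjusted), WT s_dissection 3061, KO control 21, KO sham 6, KO intact 6 and KO s_dissection 3 against WT control, and KO against WT sham 8, KO against WT intact 4, KO against WT s_dissection 5, WT intact against WT sham 2, KO intact against KO sham 615, WT s_dissection against WT intact 126, KO s_dissection against KO intact 3, the average 6 and the interaction 3. Slide as a random block gave KO control 0 (1555 unadjusted) and KO sham 119 against WT control, and KO against WT sham 17, KO s_dissection against KO intact 273, the average 968 and the interaction 106. Scan day as a fixed block gave WT sham 99, KO sham 8, KO intact 7 and KO s_dissection 88 against WT control, and KO against WT sham 7, KO against WT intact 1, KO against WT s_dissection 7, KO intact against KO sham 201, KO s_dissection against KO intact 297, the average 4 and the interaction 1. With slide as a block the sign turned for Klra1 (-0.19), Mdh1b (-0.14) and Krtap12-1 (0.83) in KO against WT intact, Tbc1d12 (0.19) in KO against WT s_dissection, and Ednrb (-0.64), Rsph4a (0.01) and Ifih1 (-0.04) in the average. It also turned for the immediate early list in KO control against WT control (-0.32) and the collagen list in KO against WT s_dissection (0.44, adjusted p = 0.030). With scan day as a block it turned for Olfr332 (-0.34), Klra1 (-0.28), Vmn2r10 (0.01), Arhgap33os (0.14) and Krtap12-1 (0.72) in KO against WT intact, for Ednrb (-0.26) and Ifih1 (-0.03) in the average, and for the macrophage list in KO intact against WT control (-0.02) and in the average (-0.35).

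Fits that used fewer arrays followed. Within the slide that holds both groups limma called WT sham 13 against WT control, and KO intact against KO sham 43, WT s_dissection against WT intact 0 (1249 unadjusted) and KO s_dissection against KO intact 0 (1656 unadjusted). Within 1 scan day it called WT sham 5 and WT s_dissection 3976 against WT control, and WT intact against WT sham 206, KO intact against KO sham 0 (2745 unadjusted), WT s_dissection against WT intact 2 and KO s_dissection against KO intact 6. Fits of only the groups compared gave WT sham 405, WT intact 246, WT s_dissection 2982, KO control 0 (2894 unadjusted), KO intact 1896 and KO s_dissection 3155 against WT control, and KO against WT sham 15, KO against WT s_dissection 0 (3179 unadjusted), WT intact against WT sham 0 (3319 unadjusted), KO intact against KO sham 0 (3881 unadjusted), WT s_dissection against WT intact 0 (3095 unadjusted), KO s_dissection against KO intact 1 and the interaction 119. Without slide 6 the counts were WT sham 4, WT s_dissection 2486, KO control 0 (1375 unadjusted) and KO sham 383 against WT control, and KO against WT sham 305, KO against WT s_dissection 1147, KO intact against KO sham 209, WT s_dissection against WT intact 0 (2042 unadjusted), the average 2429 and the interaction 75. With the sham difference subtracted and slide 6 left out they were KO against WT intact 1 and KO against WT s_dissection 64, and Klra1 turned to -0.77 in the first and -0.30 in the last. Without 3 arrays that stand apart (WT s_dissection replicate 1, WT intact replicate 6 and KO sham replicate 1) they were WT sham 153, WT intact 525, WT s_dissection 4022 and KO control 5 against WT control, and KO against WT sham 412, KO against WT s_dissection 1094, WT intact against WT sham 43, WT s_dissection against WT intact 21, KO s_dissection against KO intact 888 and the interaction 441.

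Replicate numbers were tried as a block because the labels number the samples alike in every group. No comparison had a correlation over 0.1 in every pair of equal numbers, so the numbers do not pair the samples and this block is given here alone. With the replicate block the counts were WT sham 28, WT intact 444 and KO control 0 (1533 unadjusted) against WT control, and KO against WT sham 20, WT intact against WT sham 34, KO intact against KO sham 188, WT s_dissection against WT intact 1, KO s_dissection against KO intact 72 and the interaction 83.

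Leaving out 1 array at a time, the lowest and highest counts against WT control were 2 to 44 for WT sham, 326 to 900 for WT intact, 3692 to 7183 for WT s_dissection, 0 to 1 for KO control, 3 to 329 for KO sham, 1612 to 4148 for KO intact and 3471 to 7783 for KO s_dissection. They were 0 to 206 for KO against WT sham, 878 to 1597 for KO against WT intact, 867 to 4042 for KO against WT s_dissection, 32 to 219 for WT intact against WT sham, 63 to 1301 for KO intact against KO sham, 0 to 2069 for WT s_dissection against WT intact, 0 to 2966 for KO s_dissection against KO intact, 971 to 2222 for the average and 13 to 319 for the interaction. Of the called genes that the naming rule selects, those that kept their call in every one of these fits numbered 15 of 28 for WT intact, 45 of 50 for WT s_dissection, 19 of 23 for KO intact and 29 of 29 for KO s_dissection against WT control. Elsewhere they numbered 10 of 13 for KO against WT intact, 13 of 25 for KO against WT s_dissection, 2 of 10 for WT intact against WT sham, 6 of 18 for KO intact against KO sham, 17 of 22 for the average, 2 of 6 for the interaction, and 0 for the 6 comparisons left.

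Socs3 in the average ran from 0.23 to 0.94 over the alternatives (adjusted p = 0.13 to 1.0), in WT s_dissection against WT control from 1.00 to 1.55 (adjusted p = 0.016 to 0.30) and in KO s_dissection against WT control from 1.63 to 2.90 (adjusted p = 7.4e-05 to 0.29). In KO against WT s_dissection it ran from 0.37 to 1.64 (adjusted p = 0.043 to 0.69). Rasal2 in KO control against WT control ran from -0.78 to -0.49 (adjusted p = 0.021 to 0.44). Over all alternatives, 6074 values of named genes stayed called or uncalled, uncalled sign turns included. Of the rest, 3 gained and 1716 lost the call, and 19 turned sign with a call in either fit. For the lists these numbers were 670, 5, 116 and 4.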

Other observations

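The exact test of the clock score was set before its result was seen. The splits of the samples were chosen after the result was seen.

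The WT l_dissection array differed from WT control in cell types and states that the report leaves out, as values of 1 array with no test. Platelet and red cell genes were higher, with a list median of 5.37 and all 10 members above the range of the other 37 arrays, among them the platelet chemokine Ppbp (9.60) and receptor Gp9 (7.72), each well above background on 2 of 4 WT control arrays, and the globin Hbb-bs (5.74). Hypoxia and glycolysis genes had a median of 1.35 (12 of 16 above the range) and white adipocyte markers 2.16 (8 of 9), with Adipoq at 3.18 and Plin1 at 2.68. Fibroblast markers were lower (median -1.76, 10 of 13 below the range), Pi16 by -3.29 and the proteoglycan Dcn by -2.86. Skeletal muscle markers went both ways, Tnni2 at 5.02 and Acta1 at -3.44, around a median of -2.22. Ucp1 of brown fat, well above background on 1 of 4 WT control arrays, was 7.49 higher while its list had a median of 0.55, and Schwann markers went both ways around 0.09, Mbp at 4.29 and Prx at -2.73. Alternatively activated macrophage genes had a median of 2.22, calcification genes -0.82, TGF-beta genes -0.44, renin-angiotensin genes -0.62, endothelial genes -0.23, sympathoadrenal genes 0.70, immediate early genes 0.54 and fatty acid oxidation genes 0.09.

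Clock genes were among the largest falls against WT control, Cry1 in WT sham (at least 2.21-fold lower, adjusted p = 0.016) and Per2 in KO intact (-2.24 ± 0.61, adjusted p = 0.014). A score of genes that peak by day minus genes that peak late at night, without Cry1 and Per2 (9 day and 4 late-night genes, of 15 listed and measured), was 3.83 ± 0.31 in WT control and 0.18 ± 0.63 in WT sham (n = 4 each, exact permutation p = 0.029, the smallest these arrays allow). It was 3.91 ± 0.84 in KO control, 3.30 ± 2.46 in KO sham, 2.11 ± 2.80 in WT intact, 1.24 ± 2.84 in KO intact, 1.63 ± 1.65 in WT s_dissection, 1.16 ± 2.61 in KO s_dissection and -0.60 on the WT l_dissection array. A candidate explanation is the time of day of tissue collection, which the labels do not give, and a change of the clock by the operation stays open as untested. The fall of Cry1 stays open too, since Cry1 was listed as a late-night gene and the 4 others differed by 0.68 to 4.50 in WT sham, none of them passing.

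Other splits of the same arrays were refitted to ask how many call as many genes as the groups do, real split included. The splits exchanged arrays across slides and scan days, so they leave scan day open. Against WT control no other split tried called as many for WT sham (63 genes, highest other split 1, 1 of 35 splits as large), WT intact (790, 84, 1 of 100), WT s_dissection (6071, 589, 1 of 35), KO sham (181, 26, 1 of 35), KO intact (3482, 2878, 1 of 100) and KO s_dissection (6330, 3384, 1 of 35), and elsewhere for KO sham against WT sham (36, 4, 1 of 35) and KO intact against WT intact (1403, 656, 1 of 100). It also can for the average KO minus WT (1580, 19, 1 of 100) and the interaction (214, 0, 1 of 100), and for WT intact against WT sham (111, 113, 2 of 100), KO intact against KO sham (395, 1973, 3 of 100) and WT s_dissection against WT intact (581, 966, 3 of 100). With scan day as a block limma called 7 and 1 genes for KO against WT sham and intact, 4 for the average and 1 for the interaction. Chance cannot be excluded for KO control against WT control (2, 4, 2 of 35), KO s_dissection against WT s_dissection (2552, 2913, 3 of 35) or KO s_dissection against KO intact (454, 7132, 10 of 100). Splits calling several times the real count point to a structure other than the groups. The split with 7132 genes moved replicates 1 and 2 of KO intact and KO s_dissection.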
